A study of Mus musculus with 6 samples.

How the data were processed

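Gene expression was measured by RNA sequencing in mouse splenic CD11c+ dendritic cells, the antigen-presenting cells of the spleen. Per the labels' protocols, the cells were enriched by magnetic sorting on an autoMACS instrument, and libraries came from DNase-treated total RNA with a stranded mRNA kit. The labels give 3 libraries of cells treated with IL-33, a cytokine of the IL-1 family, and 3 libraries of cells treated with PBS. They do not say whether the cells were treated in the animal or in culture, nor the dose or the time. They also do not say that the 3 libraries of a group came from separate animals or cultures. All p-values therefore measure the spread between these libraries, which may be technical.

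The authors deposited 1 table per library with a symbol and an FPKM value (fragments per kilobase of transcript scaled to the mapped fragments) for each of 24346 genes. The submitters' processing notes name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19, Cuffnorm 2.2.1 and the mouse build mm10. The gene annotation, the between-library scaling method of Cuffnorm and its use of strand are not given in the sources used here. Reads shared between near-identical genes could have been divided among them, so values of Ear and Rnase2a, Klra, Gbp, histone, ribosomal protein and H2 genes are uncertain as to the individual gene. The same holds for overlapping genes.

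FPKM values carry no read counts, so the absolute depth of the libraries is unknown. Among genes of at most 0.3 FPKM the values fell in steps of 1 fragment. Comparing these steps over 1265 to 2057 genes per library gave depths between 0.946 and 1.21 relative to PBS replicate 1, on the scale of the authors' normalization. Depth therefore did not separate the groups. The sum of FPKM did: it was 841884, 778391 and 782587 in the IL-33 libraries and 614522, 641412 and 640736 in the PBS libraries. Across tested genes, log2 values of libraries of 1 group correlated at 0.969 to 0.982 (Pearson), and those of different groups at 0.931 to 0.954. At most 8 tested genes had an identical value in any pair of libraries. In total 51 features were listed at 0 in 1 library and at 100 FPKM or more in another, and 47 of them were microRNA or small nucleolar RNA genes. An exact 0 may thus be a failed estimate, and a gene is said only to be listed at 0.

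Values were analysed as log2(FPKM + 1). The pseudocount of 1 understates the change of genes of low expression. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 11518. The model was limma (limma 3.58.1, R 4.3.3) with a moderated variance that follows the mean, 1 coefficient for treatment and no block. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all tested genes, and the threshold was an adjusted p of 0.05. Changes are IL-33 minus PBS on the log2(FPKM + 1) scale with their standard error (SE), and levels are mean ± SD in FPKM with n = 3 per group. Semaphorin genes were also given an exact two-sided permutation test of 3 against 3 libraries, whose smallest possible p is 0.1.

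The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. In all, 52 gene lists were written from textbook knowledge. They cover semaphorins and their receptors, IL-33 signalling, cytokine responses, antigen presentation, metabolism, the cell cycle, stress responses and markers of the cell types that a CD11c sort of spleen could hold. Lists with at least 5 tested members, 50 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists. Camera was also run with the correlation estimated from the data, and limma's fry was run beside it. The list of mitochondrially encoded transcripts was not analysed here, since none of its symbols were matched. Genes were named under 4 parts of 1 rule. These were Sema4a, Il1rl1 and Il1rap; the 12 largest rises and 12 largest falls past the threshold with separated groups, without predicted genes, small RNAs or antigen receptor segments; up to 4 members with the smallest adjusted p of each list that was called or had at least 3 members past the threshold; and every tested semaphorin. A gene that the rule takes is not reported here. Where another gene is named, it was chosen after its values were seen, which is said there.

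Alternatives were other pseudocounts, no filter or a filter of 5 FPKM, 3 other scalings, other variance settings, the replicate number as a block, library weights, a minimum 2-fold change, leaving out each library in turn, and other list tests. The replicate numbers shared by the groups were not treated as pairs. Positions, transcript lengths and GC content came from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, to which 23310 symbols were matched. Of the tested genes, 11090 (96.3%) had a length. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

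The model was tested on simulated data drawn for the 11518 genes of this comparison, with 50 genes changed at each of 4 sizes. It recovered 64% of those changed by 0.5 on the log2 scale, 82% at 1, 90% at 2 and 100% at 4, with 11 false calls among 179. Of 20 lists drawn at random from all simulated genes, changed ones included, 1 was called. The simulated genes varied independently and few were changed, so this does not measure how often lists are called falsely in the real data.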

Results

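RNA sequencing was used to compare splenic CD11c+ dendritic cells treated with IL-33 (3 libraries) with cells treated with the vehicle PBS (3 libraries). IL-33 is an alarmin released by damaged barrier tissue, and its receptor chain ST2 is encoded by Il1rl1. The series title names Sema4a, a membrane semaphorin of antigen-presenting cells, as a gene that dendritic cells express in response to IL-33. The comparison therefore asks what IL-33 changed in these cells, Sema4a included. The tables listed 24346 genes per library, of which 17265 were above 0 in at least 1 library and 11518 passed the expression filter and were tested. Relative depth, read from the steps between low FPKM values, lay between 0.946 and 1.21 times that of PBS replicate 1 and did not separate the groups.

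The IL-33 libraries held far more transcript of type 2 response genes and of eosinophil granule genes, and less transcript of T cell and natural killer (NK) cell genes. Retnla, a secreted product of alternatively activated macrophages, stood at 3.08 ± 1.84 FPKM with PBS and 2429 ± 1319 FPKM with IL-33, a log2 change of 9.19 (SE 0.42, n = 3 per group, adjusted p = 4.47e-05). Aldh1a2, which makes retinoic acid, rose from 2.73 ± 0.53 to 66.8 ± 2.63 FPKM (log2 change 4.19, SE 0.11, adjusted p = 4.22e-06). The chemokine receptor gene Cx3cr1 fell from 35.0 ± 1.81 to 6.80 ± 1.56 FPKM (log2 change -2.22, SE 0.14, adjusted p = 0.00011). With limma, 3230 genes were higher with IL-33, 2939 were lower and 5349 did not pass the threshold. The change was at least 2-fold for 358 of the higher and 220 of the lower genes. The 3 IL-33 libraries lay entirely above or below the 3 PBS libraries for 63.6% of tested genes, where chance gives 10%. The higher genes made up 52.4% of calls as deposited but 17.9% with libraries rescaled to equal totals (1277 higher, 5839 lower), a scaling that moved the median change of all genes from 0.01 to -0.30.

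**Figure D1:**
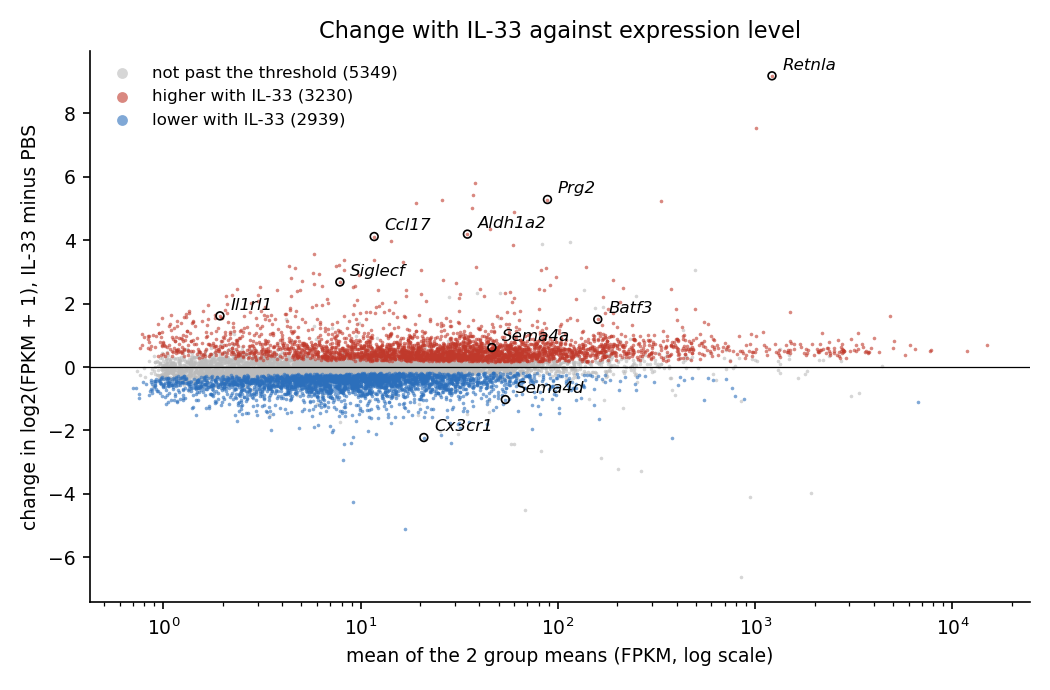
Change in log2(FPKM + 1), IL-33 minus PBS, against the mean of both group means in FPKM on a log scale, with 1 point per tested gene. Points in red (3230) and blue (2939) passed the threshold upwards and downwards, grey points (5349) did not, and circled genes are named in the text.

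The next largest rises included granule genes of eosinophils (Prg2, Ear1 and Ear6) and genes that IL-4 and IL-13 induce (Chil3, Arg1 and Mgl2). With Fcrls, Fn1 and Ccl17, these had log2 changes from 4.12 (Ccl17) to 5.82 (Fcrls). Chil3 is also a listed monocyte marker, Mgl2 a listed marker of type 2 conventional dendritic cells and Arg1 a listed marker of group 2 innate lymphoid cells. Rnase2a was listed at 0 in all 3 PBS libraries and at 175, 36.6 and 11.2 FPKM in IL-33 replicates 1, 2 and 3. The libraries of the IL-33 group differed widely for some of these genes. Arg1, the arginase of alternative activation, reached 183, 25.6 and 9.88 FPKM in replicates 1, 2 and 3, against 0.161, 0.148 and 0.177 FPKM with PBS. Among the largest falls, beside Cx3cr1, were those of the apolipoprotein gene Apoc2 (log2 change -2.40, SE 0.32), of Ly6i and of the lymphocyte genes Klra23, Il18r1, Cd8b1, S1pr5, Cd3e and Ms4a4b, which lay between -2.95 (Klra23) and -1.94 (Ms4a4b). The flagellin receptor gene Tlr5 fell from 6.21 ± 0.77 to 0.82 ± 0.34 FPKM (SE of the log2 change 0.16, adjusted p = 0.000259). PBS replicate 3 held the most transcript of several of these, such as Cd8b1 at 77.9 FPKM against 32.3 and 19.7 in PBS replicates 1 and 2. For Gzmk the same library decided the size of the fall, which was -2.42 with all libraries and -1.29 without PBS replicate 3, and the call was lost without any other single library except PBS replicate 2.

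Sema4a was higher in every IL-33 library than in every PBS library. It stood at 36.4 ± 4.97 FPKM with PBS and 56.1 ± 5.02 FPKM with IL-33, 1.54-fold more, with a log2 change of 0.62 (SE 0.11, n = 3 per group, limma adjusted p = 0.00391). The individual values were 40.7, 31.0 and 37.5 FPKM with PBS and 56.2, 61.1 and 51.1 FPKM with IL-33. Sema4a is a protein-coding gene on the minus strand of chromosome 3, from 88435959 to 88461182 in mm10. The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. The change lay at percentile 89 of the 500 tested genes nearest to it in expression, whose median change was 0.18. With libraries rescaled to equal totals the change was 0.28 (adjusted p = 0.0832, in a range of 0.00229 to 0.0832 over all alternatives), which lay 0.59 above the median of all genes under that scaling, compared with 0.61 as deposited. Quantile normalization gave 0.441 (0.455 above the median, limma adjusted p = 0.0236) and cyclic loess 0.442 (0.436 above, limma adjusted p = 0.0204). Length and GC correction gave 0.519 (0.543 above, limma adjusted p = 0.00689).

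Of the 8 tested semaphorins, 2 rose, 3 fell and 3 did not pass, over all genes and likewise adjusted over the list alone. The largest change was a fall of Sema4d (CD100), from 72.9 ± 4.83 to 35.4 ± 4.20 FPKM (log2 change -1.03, SE 0.10, adjusted p = 0.00042). Sema4c fell from 3.68 ± 0.62 to 1.77 ± 0.19 FPKM (log2 change -0.75, SE 0.12, adjusted p = 0.00248). Sema7a (log2 change 0.35, adjusted p = 0.0454) and Sema4b (-0.26, adjusted p = 0.0468) passed narrowly. The call of Sema7a was lost without IL-33 replicates 2 or 3 or any 1 PBS library (0.24 to 0.38) and with equal totals (0.03). That of Sema4b was lost without IL-33 replicates 2 or 3 or PBS replicates 1 or 2 (-0.26 to -0.20). The changes of Sema4f (0.14, SE 0.13), Sema6a (-0.20, SE 0.14) and Sema6d (-0.09, SE 0.20) did not pass, although that of Sema6a did with equal totals (-0.45). As a list the semaphorins had a median change of -0.14, which turned to 0.11 after removal of trends with transcript length and GC content, and camera did not call them (adjusted p = 0.495). The test by fry did call them, downwards (fry adjusted p = 0.0101). With equal totals none were higher and 4 lower (median -0.43), and without a filter 1 of 19 was higher and 3 lower (-0.02). With 1 library left out the median lay between -0.24 (without PBS replicate 1) and -0.04 (without PBS replicate 3). Among 9 tested plexins, neuropilins and other semaphorin receptors, 2 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.838). Nrp2 rose from 1.16 ± 0.22 to 11.6 ± 0.56 FPKM (log2 change 2.55, SE 0.10) and Plxnd1 rose by 1.11 (SE 0.08), whereas Cd72 fell by 1.16 (SE 0.12) and Plxnc1 by 0.99 (SE 0.14). The mean change of that list was 0.13 while its median was -0.02 (-0.36 with equal totals) and camera's direction was down.

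**Figure D2:**
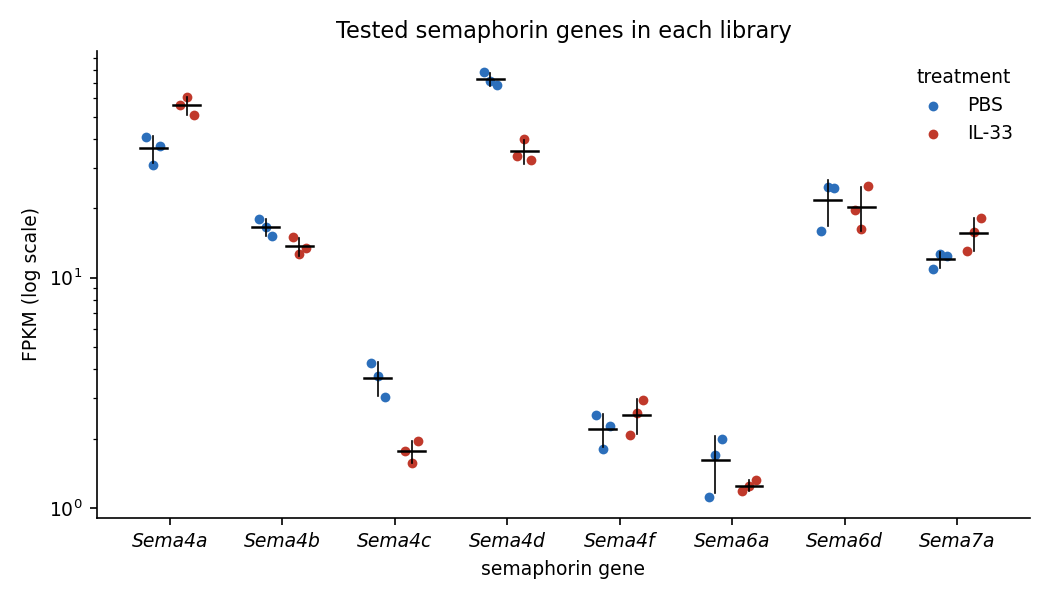
FPKM (log scale) of the 8 tested semaphorin genes in each of the 3 PBS and 3 IL-33 libraries. Points are libraries, horizontal bars group means and vertical bars ± SD, and the IL-33 points of Sema4a (51.1 to 61.1 FPKM) all lie above its PBS points (31.0 to 40.7 FPKM), and those of Sema4d all lie below.

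The receptor gene Il1rl1 rose from 0.44 ± 0.05 to 3.43 ± 0.51 FPKM (log2 change 1.61, SE 0.12, adjusted p = 0.000201). Il1rl1 is also on the list of innate lymphoid cell markers, and which of the sorted cells held its transcript was not tested. Its co-receptor gene Il1rap was at 2.91 ± 0.18 and 2.15 ± 0.45 FPKM and did not pass (log2 change -0.32, SE 0.13, adjusted p = 0.0634), except with equal totals (-0.62, adjusted p = 0.00577, in a range of 0.00577 to 0.278 over alternatives). Of 15 tested genes of the IL-33 receptor and its proximal signalling, 3 rose and 4 fell, as they did adjusted over the list alone, but 2 were higher and 9 lower with equal totals (median -0.50). The adaptor gene Myd88 rose by 0.57 (SE 0.07) while Chuk and Tab2 fell by 0.36 (SE 0.07) and 0.43 (SE 0.08), and camera did not call the list (adjusted p = 0.583, median -0.17, mean 0.03). In the list of NF-κB feedback and target genes 11 of 21 rose and 4 fell, the same adjusted over the list alone. Tnip3 (log2 change 2.95, SE 0.15) and Tnfaip3 (0.83, SE 0.12) rose and Nfkb1 fell (-0.62, SE 0.07). Camera did not call that list (adjusted p = 0.231), and its median of 0.19 turned to -0.14 with equal totals (4 higher, 7 lower), -0.06 with quantile normalization (5 and 6) and -0.08 with cyclic loess (5 and 6).

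Most of the genes that IL-4 and IL-13 induce through STAT6 rose. Of 20 tested, 13 rose and 1 fell (Fcer2a, whose call was lost without IL-33 replicate 3, at -1.12), likewise adjusted over the list alone, with a median log2 change of 1.34 (camera adjusted p = 0.000216, adjusted p = 0.509 with an estimated correlation). Ccl24 rose from 6.76 ± 1.05 to 112 ± 31.0 FPKM (log2 change 3.84, SE 0.21) and the lectin gene Cd209e from 6.15 ± 1.82 to 46.2 ± 6.01 FPKM (log2 change 2.75, SE 0.20). The call was lost when the 14 members shared with other lists were left out (median 0.11, adjusted p = 0.221, in a range of 1.66e-08 to 0.509 over alternatives). Chemokines rose too, 12 of 18 tested and 3 falling, or 13 and 3 adjusted over the list alone (median 1.76, camera adjusted p = 0.00193, adjusted p = 0.509 with an estimated correlation). Ccl9 rose by 2.59 (SE 0.19) and Ccl6 by 2.47 (SE 0.19). Only 14 of the 26 listed chemokines were at 1 FPKM or more with PBS, so the filter favoured members higher with IL-33. Without a filter 13 of 24 rose and 1 fell (median 1.13), and without IL-33 replicate 1 the median was 1.27. Genes of the GM-CSF and STAT5 response rose in 15 of 20 cases with none falling, and the counts were the same adjusted over the list alone. Their median change was 0.68 (camera adjusted p = 6.5e-05, adjusted p = 0.509 with an estimated correlation). Fabp5 (log2 change 2.21, SE 0.13), Clec7a, which encodes the glucan receptor dectin-1 (1.82, SE 0.11), and the interleukin-1 antagonist gene Il1rn (1.52, SE 0.14) were examples. With equal totals 10 of the list were higher and 2 lower (median 0.35), with quantile normalization 11 and 1 (0.44) and with cyclic loess 11 and none (0.44).

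Type 2 cytokine transcripts were low. Only 3 of the 10 listed genes passed the expression filter, and 1 of them was at 1 FPKM or more with PBS, so the filter favoured genes that were higher with IL-33. The 3 rose, over all genes and adjusted over the list alone: Areg (0.53 ± 0.22 to 3.44 ± 0.27 FPKM), Il4 (0.77 ± 0.42 to 2.94 ± 1.07 FPKM) and Tslp. Without a filter 7 were tested, of which 4 rose and none fell, or 5 and none adjusted over the list alone. The call of Tslp was lost when any 1 library other than PBS replicate 2 was left out. Of 17 inflammatory cytokines 9 rose and 2 fell, the same adjusted over the list alone. Il6 went from 0.75 ± 0.16 to 9.05 ± 4.80 FPKM and Il10 from 1.42 ± 0.34 to 6.86 ± 1.88 FPKM, while Ltb fell by 0.97 (SE 0.11). Camera did not call the list (adjusted p = 0.12, median 0.32, and -0.02 with equal totals, where 6 were higher and 5 lower).

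Eosinophil markers rose beside the STAT6 genes. Of 10 tested, 8 rose and none fell, also adjusted over the list alone (median 2.88, camera adjusted p = 0.000105, adjusted p = 0.509 with an estimated correlation). The granule protein gene Prg2 rose from 3.40 ± 0.43 to 174 ± 43.3 FPKM (log2 change 5.29, SE 0.18). Siglecf, an eosinophil surface lectin, rose from 1.39 ± 0.27 to 14.3 ± 0.76 FPKM (log2 change 2.68, SE 0.10). The receptor genes Ccr3 (51.2 ± 14.5 and 51.4 ± 13.8 FPKM) and Il5ra (1.79 ± 1.10 and 1.30 ± 0.21 FPKM) did not pass, and are named because of their values. Mast cell and basophil markers rose in 7 of 11 cases and fell in 2, as they did adjusted over the list alone, without a camera call (adjusted p = 0.082, median 1.01). Only 4 of the 20 listed genes were at 1 FPKM or more with PBS, so the filter favoured members higher with IL-33, and without a filter 12 of 20 rose and 2 fell (median 0.55). Camera called this list without IL-33 replicate 3 (median 1.16, adjusted p = 0.0374, in a range of 0.00053 to 0.65 over alternatives). Basophil protease genes were among them, with Mcpt8 going from 0.32 ± 0.20 to 8.57 ± 3.07 FPKM and Prss34 rising by 2.53 on the log2 scale (SE 0.24). The 11 tested markers of group 2 innate lymphoid cells were split, with 4 higher and 5 lower, the same adjusted over the list alone (adjusted p = 0.957). Their median was -0.08, their mean 0.39 and camera's direction up, and the median was 0.05 with cyclic loess and 0.01 with quantile normalization. It was -0.38 with equal totals and -0.38 after length and GC correction. With 1 library left out it lay between -0.42 (without PBS replicate 2) and 0.07 (without IL-33 replicate 3).

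Neutrophil and plasma cell transcripts were also more abundant with IL-33. Of 17 neutrophil markers 13 rose and 2 fell, also adjusted over the list alone (median 1.36, camera adjusted p = 0.00464, adjusted p = 0.66 with an estimated correlation). Retnlg rose from 25.3 ± 4.35 to 144 ± 38.9 FPKM and Ngp from 9.58 ± 3.26 to 53.9 ± 25.2 FPKM. Of 13 plasma cell markers 10 rose and 1 fell, or 11 and 1 adjusted over the list alone (median 1.08, camera adjusted p = 0.000848, adjusted p = 0.509 with an estimated correlation). Jchain, the joining chain of secreted IgA and IgM, rose from 46.2 ± 16.3 to 200 ± 20.3 FPKM and Mzb1 from 28.5 ± 10.9 to 90.8 ± 4.20 FPKM. Macrophage markers rose in 6 of 19 cases with none falling, but in 1 case adjusted over the list alone (adjusted p = 0.234). Their median was 0.31 as deposited, -0.03 with equal totals (none higher, 2 lower) and -0.01 with cyclic loess (2 and 2). The median was 0.04 without PBS replicate 1 and 0.19 without IL-33 replicate 3, while the list was called without IL-33 replicate 2 (median 0.46, adjusted p = 0.0448) or PBS replicate 3 (0.47, adjusted p = 0.045), in a range of 0.0448 to 0.917 over alternatives. Monocyte markers were split 5 and 5 among 19, likewise adjusted over the list alone (adjusted p = 0.838, median 0.14 and mean 0.50, with a median of -0.20 with equal totals (3 higher, 7 lower), -0.19 with quantile normalization (4 and 8), -0.26 with cyclic loess (4 and 8) and -0.08 after length and GC correction).

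T cell and NK cell transcripts fell together. Among 20 T cell markers 17 fell and 1 rose, or 17 and 2 adjusted over the list alone (median -1.51, camera adjusted p = 0.000135, adjusted p = 0.558 with an estimated correlation). The T cell receptor chain gene Cd247 fell from 21.1 ± 5.50 to 6.36 ± 1.57 FPKM (log2 change -1.57, SE 0.22) and the transcription factor gene Tcf7 from 48.1 ± 5.99 to 17.6 ± 0.96 FPKM (-1.39, SE 0.10). Ctla4, an inhibitory receptor of activated and regulatory T cells, rose from 3.09 ± 0.67 to 9.38 ± 1.57 FPKM. Among 20 NK cell markers 17 fell and none rose, also adjusted over the list alone (median -1.35, camera adjusted p = 1.59e-06, adjusted p = 0.509 with an estimated correlation). Klrd1 fell from 166 ± 13.1 to 80.1 ± 4.48 FPKM and Eomes from 9.56 ± 1.15 to 2.88 ± 0.67 FPKM. Of 17 B cell markers 4 fell and none rose, or 3 and none adjusted over the list alone, without a camera call (median -0.38, adjusted p = 0.133). The median rested on single libraries: it was -0.04 without PBS replicate 1 (adjusted p = 0.741), and without PBS replicate 3 the list was called (median -0.62, adjusted p = 0.0043, in a range of 0.0043 to 0.871 over alternatives). Cd22 and Cr2 were among those that fell, by 0.92 (SE 0.20) and 1.16 (SE 0.27).

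Markers of the dendritic cell types themselves moved in both directions. Of 20 markers of type 1 conventional dendritic cells 6 rose and 8 fell, or 6 and 10 adjusted over the list alone (median -0.27, camera adjusted p = 0.403). The median was -0.61 with equal totals (4 higher, 13 lower), -0.26 with quantile normalization (3 and 9), -0.22 with cyclic loess (3 and 9) and -0.09 after length and GC correction (4 and 7). Batf3, a transcription factor needed by these cells, rose from 82.4 ± 5.61 to 236 ± 20.1 FPKM (2.86-fold, SE of the log2 change 0.09), and Itgae rose by 2.10 (SE 0.15). The chemokine receptor gene Xcr1 fell from 15.2 ± 1.29 to 7.65 ± 0.83 FPKM (-0.91, SE 0.10), and Tlr3 fell by 1.03 (SE 0.10). Type 2 conventional markers were split 8 higher and 6 lower of 20, as they were adjusted over the list alone (adjusted p = 0.957). Their median was 0.09 and their mean 0.11, with camera's direction down, and the median turned to -0.26 with equal totals (4 higher, 11 lower), -0.24 with quantile normalization (4 and 10), -0.24 with cyclic loess (4 and 10) and -0.05 after length and GC correction. Plasmacytoid dendritic cell markers fell in 10 of 20 cases and rose in 4, also adjusted over the list alone (median -0.53, camera adjusted p = 0.0295, adjusted p = 0.65 with an estimated correlation). Siglech, a surface lectin of these cells, fell from 51.1 ± 12.7 to 12.4 ± 0.84 FPKM. The camera call was lost without IL-33 replicate 3 (median -0.45, adjusted p = 0.0627, in a range of 0.00134 to 0.65 over alternatives) and with equal totals (median -0.87, 1 higher, 14 lower).

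**Figure D3:**
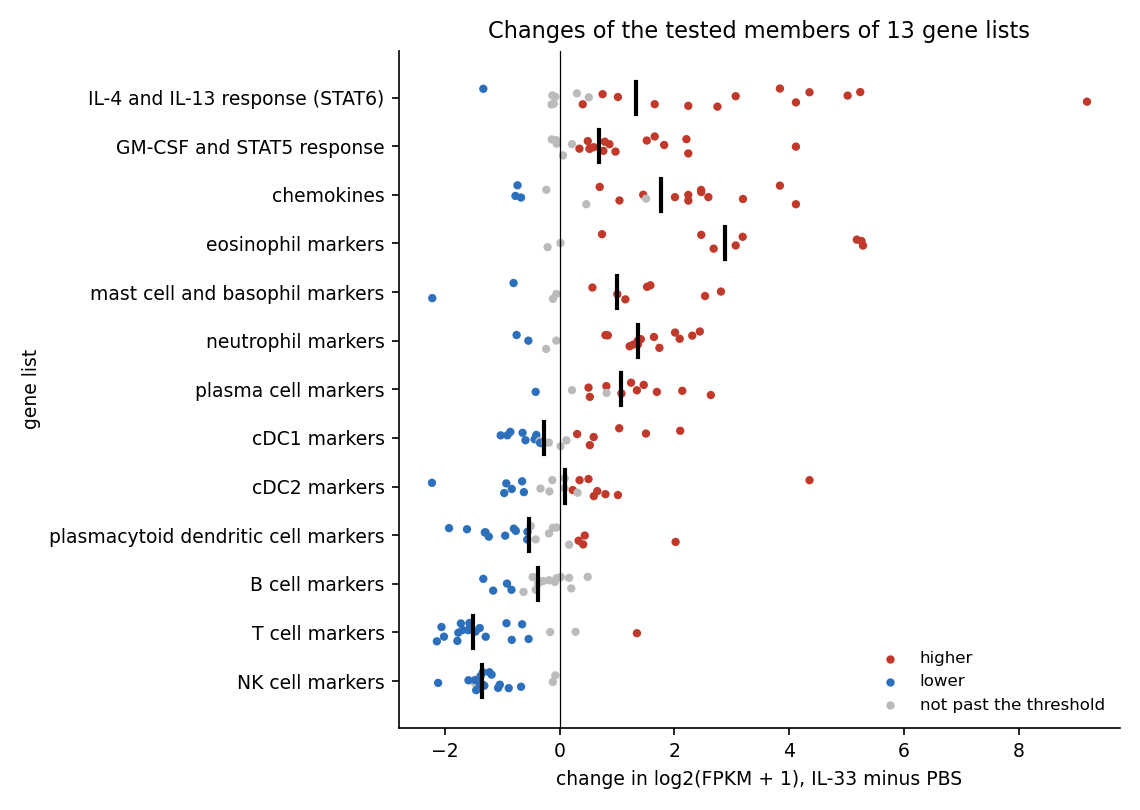
Change in log2(FPKM + 1), IL-33 minus PBS, of each tested member of 13 gene lists, 1 point per gene, red where higher, blue where lower and grey where not past the threshold, with cDC1 and cDC2 for type 1 and type 2 conventional dendritic cells. Black bars are list medians, which run from -1.51 for T cell markers to 2.88 for eosinophil markers, and the cDC2 median (0.09) turned to -0.24 with quantile normalization, -0.24 with cyclic loess, -0.26 with equal totals and -0.05 after length and GC correction.

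Antigen presentation genes rose in part as deposited, with counts that turned under other scalings. Of 15 MHC class II presentation genes 9 rose and 2 fell, likewise adjusted over the list alone (median 0.52, camera adjusted p = 0.0324, adjusted p = 0.595 with an estimated correlation). Ifi30, a lysosomal thiol reductase, rose from 693 ± 12.2 to 1495 ± 88.0 FPKM and the peptide exchange gene H2-DMa from 280 ± 5.67 to 520 ± 34.9 FPKM. This call was lost without IL-33 replicate 3 (median 0.54, adjusted p = 0.0769, in a range of 0.00159 to 0.695 over alternatives), and the median was 0.18 with equal totals (6 higher, 5 lower), 0.09 with quantile normalization (4 and 5), 0.17 after length and GC correction (6 and 2) and turned to -0.09 with cyclic loess (3 and 5). Of 20 MHC class I genes 7 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.421), and their median of 0.15 turned to -0.19 with equal totals (none higher, 9 lower), -0.21 with quantile normalization (none and 9), -0.22 with cyclic loess (none and 10) and -0.05 after length and GC correction (none and 3). Costimulatory and inhibitory ligands were split 3 and 3 of 13, also adjusted over the list alone (adjusted p = 0.883). Icosl fell by 0.64 (SE 0.07) and Cd40 by 0.38 (SE 0.06), and Pdcd1lg2, which encodes PD-L2, rose by 0.75 (SE 0.11). Their median of 0.15 turned to -0.19 with equal totals (2 higher, 5 lower) and -0.08 after length and GC correction. The mature migratory programme had 9 of 23 members higher and 6 lower, the same adjusted over the list alone (adjusted p = 0.25), and its median of 0.18 turned to -0.16 with equal totals (9 higher, 8 lower), -0.14 with quantile normalization (9 and 7) and -0.19 with cyclic loess (9 and 7). Cd83, a maturation marker, rose from 211 ± 39.5 to 593 ± 85.3 FPKM. Pattern recognition receptors fell in 13 of 26 cases and rose in 2, also adjusted over the list alone (median -0.20, camera adjusted p = 0.0493, adjusted p = 0.509 with an estimated correlation). This narrow call was lost without IL-33 replicate 3, PBS replicate 2 or PBS replicate 3 (medians -0.20, -0.19 and -0.17, with adjusted p = 0.0811, 0.0673 and 0.0785, in a range of 0.00593 to 0.509 over alternatives). With equal totals 2 were higher and 19 lower (median -0.52).

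Genes of oxidative phosphorylation, ribosomal proteins and the cell cycle rose as deposited. The ribosomal counts fell sharply under other scalings, and the cell cycle counts fell sharply with equal totals. All 35 tested nuclear genes of oxidative phosphorylation rose as deposited, also adjusted over the list alone (median 0.67, camera adjusted p = 4.56e-12, adjusted p = 0.509 with an estimated correlation). Their median lay between 0.33 and 0.66 under the other scalings and corrections, with 24 to 34 genes higher. Cox8a, a subunit of complex IV, went from 287 ± 14.7 to 569 ± 45.8 FPKM. Of 53 ribosomal protein genes 51 rose and none fell, likewise adjusted over the list alone (median 0.52, camera adjusted p = 2.78e-14, adjusted p = 0.509 with an estimated correlation). Rpl28 went from 1874 ± 93.6 to 3399 ± 144 FPKM, but the median of the ribosomal list turned to -0.02 with cyclic loess (5 higher, 4 lower) and was 0.06 with quantile normalization (8 higher, 1 lower). It was 0.18 with equal totals (37 higher) and 0.22 after length and GC correction (29 higher), and both cyclic loess and quantile normalization ended the camera call. Of 36 genes of the G2 and M phases 21 rose and none fell, or 23 and none adjusted over the list alone (median 0.57, camera adjusted p = 0.00142, adjusted p = 0.721 with an estimated correlation). Of 29 S phase genes 13 rose and 1 fell, the same adjusted over the list alone (median 0.30, camera adjusted p = 0.00687, adjusted p = 0.721 with an estimated correlation). With equal totals 1 S phase gene was higher and 3 lower (median 0.01), and 7 G2 and M phase genes were higher and 2 lower (median 0.26), and these medians lay 0.31 and 0.56 above that of all genes, compared with 0.29 and 0.56 as deposited. With quantile normalization 21 G2 and M phase genes were higher and 1 lower, and 11 S phase genes were higher and none lower. Cyclic loess gave 22 and 1, and 12 and none. The test by fry called neither of these cell cycle lists. Aurkb, a mitotic kinase gene, went from 9.14 ± 2.41 to 19.5 ± 1.87 FPKM. Genes of the list written for replication-dependent histones rose in 8 of 11 cases with none falling, also adjusted over the list alone (median 0.75, camera adjusted p = 0.00464, adjusted p = 0.548 with an estimated correlation). Without a filter 9 of 18 rose (median 0.40). The list also holds H1f0 and H2afz, which are not replication-dependent, and both were among those that rose.

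These rises stood beside trends that ran across all genes. The median change was 0.42 for genes whose longest transcript was under 1000 bases and -0.47 for those of 8000 bases or more. Across 11090 genes, which are not independent replicates, the change correlated with transcript length at a Spearman rho of -0.44 and with GC content at 0.18. Across 11518 genes it correlated with expression level at 0.31. Of the 111 genes above 1000 FPKM 85.6% rose, compared with 14.9% of the 3018 genes under 5 FPKM. Further measures of the libraries separated the groups and are named because of their values. The ribosomal RNA precursor Rn45s stood at 652, 437 and 599 FPKM in IL-33 replicates 1, 2 and 3 and at 283, 294 and 317 FPKM with PBS. The nuclear noncoding transcript Malat1 stood at 50.3, 88.4 and 98.4 FPKM with IL-33 and at 293, 254 and 187 FPKM with PBS. Small RNA features, counted together with Rn45s, made up 4.73, 4.04 and 4.13% of the FPKM total with IL-33 and 8.21, 7.36 and 5.05% with PBS.

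**Figure D4:**
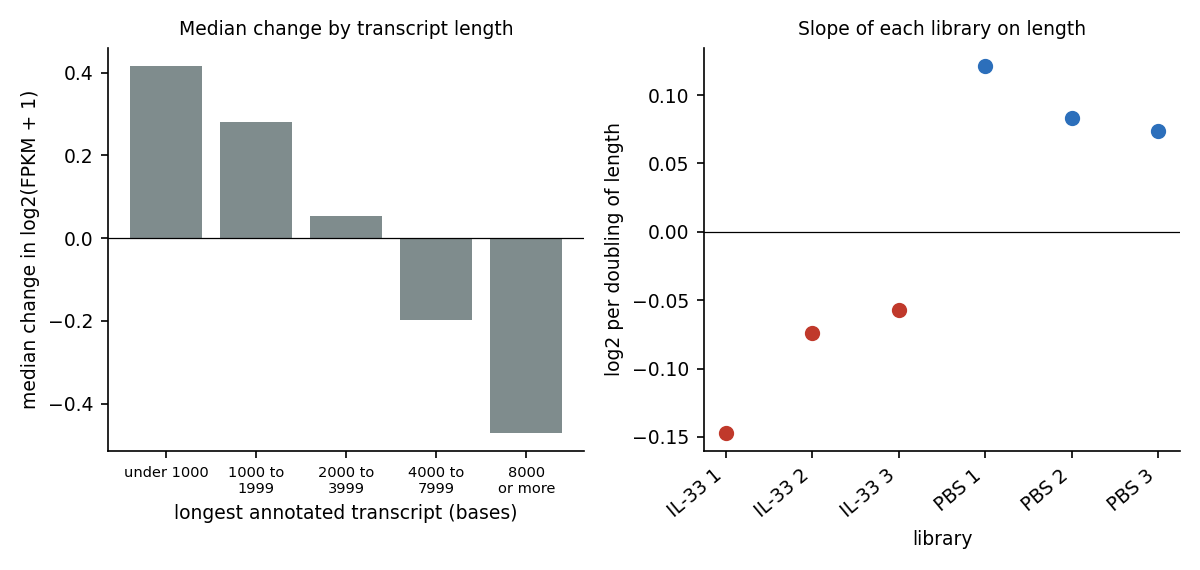
Left, median change in log2(FPKM + 1), IL-33 minus PBS, of tested genes by length of the longest annotated transcript in bases, and right, slope on log2 transcript length of each library's deviations from the gene means, in log2 units per doubling of length, with IL-33 in red and PBS in blue. The bars run from 0.42 to -0.47, and the slopes lie between -0.15 and -0.06 with IL-33 and between 0.07 and 0.12 with PBS.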

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

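The tests with cyclic loess, with length and GC correction and without short features were chosen only after seeing the data, and all other settings before. Named genes were recomputed in 19 settings, which leave out array weights and the 2-fold minimum. Of the 201 genes recomputed, 176 were tested in each of the 19, and 152 of these kept their direction and call in all. Most were named for large changes or small adjusted p in these same data, so this share does not describe called genes at large. Equal library totals gave 1277 higher and 5839 lower genes and a Sema4a change of 0.284 (adjusted p = 0.0832), because the rescaling moved the median change of all genes to -0.30. All 1277 were among the 3230 genes higher as deposited, all 2939 lower genes kept their call, and 2 calls reversed. Quantile normalization kept the call of 2331 higher and 2466 lower genes, with 10 reversed. Cyclic loess kept 2353 and 2223, with 19 reversed. Length and GC correction, over 11090 genes, kept 2051 and 1915, with 3 reversed. A minimum 2-fold change left 358 higher and 220 lower. With an estimated correlation camera called 0 lists (3 at an unadjusted p under 0.05), while fry called 33 and the preset correlation 26. In camera's direction, fry called 9 lists that the preset correlation did not, and it did not call 3 that the preset correlation called. The 9 included semaphorins (fry adjusted p = 0.0101), NF-κB feedback and target genes (0.013) and inflammatory cytokines (0.0182). Mast cell and basophil markers (0.00811) and progenitor markers (0.00762) were also among them. Calr (0.27 as deposited) was -0.073 with equal totals, -0.204 with quantile normalization and -0.169 with cyclic loess, and Hsp90ab1 was -0.005 with cyclic loess. Cyclic loess gave medians of -0.093 for MHC class II, -0.221 for MHC class I and -0.023 for ribosomal genes, and quantile normalization gave -0.206 for MHC class I. Fry called semaphorin receptors up at a median of -0.023. The cause of these reversals was not tested. With 1 library left out, 2622 to 3108 genes were higher, 2214 to 2768 lower and 22 to 28 lists called, and the Sema4a change was 0.507 to 0.699. With a replicate block the Sema4a change was 0.616 (adjusted p = 0.0132, in a range of 0.00229 to 0.0832 over alternatives), with 2806 higher and 2452 lower genes and 27 lists called. Deviations of same-numbered libraries correlated at 0.075, -0.054 and 0.089, with 4 of 6 libraries closest to their own number. These values do not settle whether the libraries were paired. The model without pairs was fixed beforehand, because no pairing is given. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) reached 6169 genes and the highest other 4, and 10 splits are too few for a share under 0.05. Depth limits genes of low FPKM, whose values rest on few fragments.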

Other observations

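The tests of eosinophils, of a STAT6 response, of the trend with expression level and of T and NK cells were chosen only after the result was seen. The matching on all 3 gene properties together was added after the separate matchings, and the margin on its limit was set after the ribosomal percentile for expression level was seen.

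Genes for making and sensing eicosanoids, the lipid mediators made from arachidonic acid, rose with IL-33. Of 16 tested, 10 rose and 2 fell, also adjusted over the list alone (median 0.50, camera adjusted p = 0.00549, adjusted p = 0.509 with an estimated correlation). The leukotriene B4 receptor gene Ltb4r1 rose by 2.64 (SE 0.22) on the log2 scale, and Cysltr1 and Ptgir by 1.95 (SE 0.11) and 1.97 (SE 0.13). With equal totals 8 of the list were higher and 3 lower (median 0.20). Targets of NRF2 and oxidative stress rose in 13 of 19 cases and fell in 1, or 15 and 1 adjusted over the list alone (median 0.51, camera adjusted p = 0.000413, adjusted p = 0.509 with an estimated correlation). With equal totals 10 were higher and 3 lower (median 0.17). The metallothionein gene Mt2 rose from 3.48 ± 0.30 to 37.0 ± 7.50 FPKM. Of 27 lysosome and phagocytosis genes 18 rose and 1 fell, likewise adjusted over the list alone (median 0.47, camera adjusted p = 0.000216, adjusted p = 0.65 with an estimated correlation), among them the scavenger receptor gene Msr1 (log2 change 1.58, SE 0.13). Tolerogenic and regulatory genes rose in 10 of 17 cases and fell in 2, the same adjusted over the list alone (median 0.40, camera adjusted p = 0.0406, adjusted p = 0.509 with an estimated correlation). With equal totals 8 lysosome genes were higher and 3 lower (median 0.13), and 7 tolerogenic genes were higher and 4 lower (0.11). Quantile normalization and cyclic loess each gave 13 lysosome genes higher and 1 lower (median 0.24 with both). The tolerogenic call was lost with quantile normalization and cyclic loess, though the median was then 0.44 with both, and after length and GC correction (0.29) or without members shared with other lists (0.30), and without a filter the median was 0.22.

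Lists of stress and biosynthesis genes differed in how many members rose, and their counts changed with the scaling. Of 21 genes of the unfolded protein response 14 rose and none fell, also adjusted over the list alone (median 0.41, camera adjusted p = 0.000799, adjusted p = 0.558 with an estimated correlation). Ddit3, a transcription factor of that response, rose from 41.8 ± 6.86 to 115 ± 6.55 FPKM, but the list's call was lost with quantile normalization (median 0.14, 9 higher, 1 lower) and cyclic loess (0.11, 8 and 1), and with equal totals 7 were higher and 3 lower (median 0.075). Amino acid and tRNA charging genes rose in 10 of 17 cases and fell in 2 (median 0.37, camera adjusted p = 0.0248), and apoptosis regulators in 14 of 24 with 1 falling, or 2 adjusted over the list alone (median 0.32, camera adjusted p = 0.0361). Both stood at adjusted p = 0.509 with an estimated correlation, the amino acid counts were the same adjusted over the list alone, and the apoptosis call was lost without IL-33 replicate 3 (median 0.32, adjusted p = 0.0627, in a range of 0.00298 to 0.509 over alternatives), its median turning to -0.01 with equal totals (5 higher, 8 lower). The amino acid median was 0.04 with equal totals (3 higher, 4 lower). Cholesterol synthesis genes rose in 10 of 22 cases with none falling, also adjusted over the list alone (median 0.32, and -0.004 with equal totals, where 3 were higher and 4 lower, camera adjusted p = 0.0246, adjusted p = 0.66 with an estimated correlation). Glycolysis genes rose in 10 of 21 and fell in 3, also adjusted over the list alone (median 0.29, and -0.05 with equal totals, where 7 were higher and 5 lower, camera adjusted p = 0.0461, adjusted p = 0.65 with an estimated correlation). Without IL-33 replicate 1 or PBS replicate 3 both calls were lost (medians 0.27 and 0.24 for cholesterol synthesis, 0.23 and 0.39 for glycolysis), and the glycolysis call also without PBS replicate 2 (0.25). Heat shock genes rose in 4 of 14 cases and fell in 1, also adjusted over the list alone (median 0.53, camera adjusted p = 0.0433, adjusted p = 0.721 with an estimated correlation), and that call was lost without IL-33 replicate 3 (0.39) or PBS replicate 1 (0.35). The share of heat shock genes that rose was close to that of all tested genes (3230 of 11518), the directional test by fry did not call the list, and with equal totals 1 gene was higher and 1 lower (median 0.21). Quantile normalization and cyclic loess each ended the calls of all of these lists except cholesterol synthesis. The glycolysis median was then 0.25 and 0.24, close to its value as deposited, while the medians for amino acid genes (0.22 and 0.22), apoptosis (0.14 and 0.14) and heat shock (0.35 and 0.33) were smaller.

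Further lists were not called by camera. Interferon-stimulated genes had 7 of 35 higher and 3 lower, or 7 and 2 adjusted over the list alone (adjusted p = 0.495), with a median of 0.02 that was -0.32 with equal totals (5 higher, 18 lower) and -0.01 after length and GC correction. Adhesion genes had 7 of 21 higher and 5 lower, the same adjusted over the list alone (adjusted p = 0.957), and their median of 0.01 turned below 0 under every other scaling or correction tried, with 2 higher and 10 lower with equal totals. Hypoxia targets had 6 of 16 higher and 1 lower, or 5 and 1 adjusted over the list alone (adjusted p = 0.421, median 0.15, and -0.17 with equal totals, where 2 were higher and 6 lower). Cholesterol efflux genes had 4 of 12 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.805), and Pltp among them rose from 47.5 ± 4.25 to 331 ± 71.8 FPKM. The median of that list was 0.02 and turned to -0.31 with equal totals (3 higher, 5 lower), -0.04 with quantile normalization and -0.02 with cyclic loess. It was 0.18 after length and GC correction. With 1 library left out it lay between -0.08 (without PBS replicate 3) and 0.14 (without IL-33 replicate 3). Immediate early genes had 9 of 25 higher and 1 lower, or 8 and 1 adjusted over the list alone (adjusted p = 0.0688, median 0.32), and were called without IL-33 replicate 2 (0.34) or PBS replicate 2 (0.41). Their median turned to -0.01 with equal totals (5 higher, 6 lower), -0.04 with quantile normalization (5 and 7) and -0.03 with cyclic loess (5 and 7). Erythroid markers had 3 of 9 higher and 1 lower (adjusted p = 0.957, median -0.53), and stromal markers 2 of 7 higher and 2 lower (adjusted p = 0.883, median -0.28), both the same adjusted over the list alone. With 1 library left out the erythroid median lay between -1.48 (without PBS replicate 3) and -0.26 (without PBS replicate 1) and the stromal median between -0.35 (without IL-33 replicate 2) and -0.05 (without PBS replicate 2). Without a filter the erythroid median turned to 0.07 (4 of 19 higher, 1 lower) and the stromal median was -0.003 (2 of 23 higher, 3 lower). Platelet markers had 4 of 8 higher and 1 lower, or 5 and 1 adjusted over the list alone (adjusted p = 0.321, median 0.52), and progenitor markers 3 of 13 higher and 5 lower, or 3 and 8 adjusted over the list alone (adjusted p = 0.329, median -0.39). With equal totals 1 platelet gene was higher and 2 lower (median 0.35), and 2 progenitor genes were higher and 9 lower (-0.72). Without a filter 6 of 20 platelet genes were higher and 2 lower (0.23), and 8 of 20 progenitor genes were higher and 5 lower (-0.03).

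The rise of eosinophil, basophil and STAT6-response genes could come from eosinophils among the sorted cells or from a STAT6 response of the cells already present, and neither was excluded. Other sources, such as basophils, macrophages or other cell types among the sorted cells, were not tested. The eosinophil list members outside the STAT6 list had a median change of 2.683, and the most abundant of those named was Ccl6, at 113 ± 14.3 FPKM with PBS and 639 ± 166 FPKM with IL-33, but Ccr3 and Il5ra, named after their values were seen, did not pass. The magnetic CD11c sort would deplete eosinophils that lack CD11c but, as an enrichment, need not remove all of them. PBS libraries held 6 of the 10 eosinophil list genes at 1 FPKM or more, and 2 of the 10 are also on other lists. Of the 13 STAT6 list members at 5 FPKM or more with PBS, 53.85% (7) rose, which lies between the bounds set for and against a response of the cells present.

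The rise of oxidative phosphorylation and ribosomal genes was weighed against the trends with expression level, transcript length and GC content. No other list was matched in this way, so the part of these trends in other rises was not tested. The oxidative phosphorylation median lay at percentile 100 of 10000 lists matched on expression level and 100 of those matched on length and GC content. It lay at percentile 99.99 of lists matched on all 3, whose typical median was 0.415, compared with 0.671 for the oxidative phosphorylation genes. Much of the rise thus went with these trends, while the remainder argues against them as its whole cause. Genes of 1 pathway may vary together more than those of matched lists, so no percentile given here is a p-value. The ribosomal median lay at percentile 99.92 of lists matched on length and GC content, which argues against that pair alone, but at 97.44 for expression level, too near the limit to decide, and at 82.21 for all 3 together, so the trends together may account for it. The gap between the groups' length slopes was 1.458 times the widest range within a group, which argues against a length bias that ignores treatment. It cannot exclude such a bias, since 6 libraries allow too few splits. A length bias that follows treatment, such as a difference in RNA quality between the groups, stays open and was not tested, and other measures moved with treatment: Rn45s lay at 437 to 652 FPKM with IL-33 and 283 to 317 with PBS, Malat1 at 50.3 to 98.4 and 187 to 293, and the small RNA share at 4.04 to 4.73% and 5.05 to 8.21%.

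The fall of T and NK cell genes may come from fewer T and NK cells in the IL-33 sorts or from lower expression within those cells, and these cannot be told apart, since the 85% of the 40 list members (34) that fell is what either would give. The magnetic CD11c sort would deplete T and NK cells that lack CD11c but, as an enrichment, need not remove all of them. The most abundant list genes were Ccl5 and Gzma, named after their values were seen. They stood at 946 and 208 FPKM with PBS and 579 and 96.2 FPKM with IL-33. Of the list genes PBS libraries held 19 of 23 T cell and 20 of 20 NK cell members at 1 FPKM or more, and 4 and 3 of them are also on other lists. The B cell median lay 1.007 above that of T and NK genes (95% bootstrap interval over genes 0.731 to 1.348). With 1 library left out it lay between 0.639 and 1.309 above, and the lower bound of the interval was at least 0.261. The B cell median itself then lay between -0.616 (without PBS replicate 3) and -0.035 (without PBS replicate 1). The smaller fall of B cell genes argues against a loss of B cells equal to that of T and NK cells in these libraries. No other lymphoid list was compared in this way. The interval resampled genes, which are not independent replicates, so it does not measure the spread between libraries.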
